A study of Mus musculus with 6 samples.

How the data were processed

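Total RNA was extracted from tongues of mice given 100 µg/ml of 4NQO in drinking water for 20 weeks, and a sequencing company built the libraries, per the labels' protocols. The deposited table holds FPKM values for 35275 genes, with 1 column per library and no pooling of replicates. The aligner, the counter, the genome build and the annotation release are not given in the sources used here. Of the gene IDs 34490 are in GENCODE M21, and 24912 of these (72.2%) have identical coordinates there, so coordinates are printed as the deposited table gives them and read as GRCm38. Gene symbols are those of the table, where 72 repeat an earlier symbol, and a gene listed at 0 in all libraries occurs 13055 times.

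The FPKM values deposited by the authors keep the depth. Each value times the gene length is a whole multiple of 1 step per library, within 0.01 of a read for 100% of the values above 0, and the multiples sum to the total that the step implies. The totals so recovered were 22539034, 24994421 and 21959204 reads in Aim2 KO replicates 1 to 3 and 24581427, 24273320 and 25369400 reads in wild type replicates 1 to 3. The 10 most abundant genes took 12.9% to 15.3% of the reads of a library, and genes of the mitochondrial genome took 4.01% to 5.98%. These counts set the precision of low genes such as Aim2. Because FPKM divides by the library's own total, a change in a few very abundant genes shifts all others, and this was examined by other scalings.

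Libraries were grouped by genotype as in the labels. The test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), over the 12144 genes with a mean of at least 1 FPKM across the 6 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype was the only term. For 44 lists of genes (pathways, cell type markers and tissue types of the tongue), camera was run with a preset inter-gene correlation of 0.01 on the 43 lists with at least 3 tested genes, with adjustment over the lists. Of 819 list entries 812 matched a gene of the table by symbol or ID. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Single values were compared by exact permutation tests, and shares of genes near Aim2 by Fisher's exact test.

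Genes were named by this rule: Aim2, then in each direction the 10 genes with the largest log2 difference among those past the threshold with groups that do not overlap and a symbol that is no clone or predicted name. Where fewer passed, the list was filled to 10 by the smallest unadjusted p under the same conditions. Of each list described, up to 4 members with the smallest p could be named. Casp1, Pycard, Il1b, Il18, Cxcl1, Col3a1, S100a8, H2-Q6, Trbc2, Cd5, C1qa, C1qc, Krt1, the genes near Aim2 and the genes of the closing observations were chosen after their values were seen or outside this rule.

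On simulated libraries with the real means and read totals, a biological coefficient of variation of 30% and 200 changed genes, the same test over 12081 genes recovered 26% of 50 genes raised 2-fold and 98% of 50 raised 4-fold. Of 50 genes lowered to 0.5 of their level it recovered 18%, and of 44 lowered to 0.25 it recovered 95.5%. Of its 124 calls 11 fell on unchanged genes (8.87%). In simulated libraries with no change it called 1 gene and 0 lists, with genes that varied independently, which those of real libraries do not. Every simulated gene also had the same coefficient of variation, unlike the genes of real libraries. The shares recovered therefore do not measure recovery in the real data. There Mcpt1 was 6.26-fold higher by group means and was not called (limma adjusted p = 0.504).

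Alternatives were pseudocounts of 0.1 and 0.5, no expression filter and a filter at 0.1 FPKM, median-of-ratios scaling, rescaling to TPM, quantile normalization, limma without a trend, with robust moderation, with vooma weights and with array quality weights, and the replicate number as a block. Further ones were the skeletal muscle level as a covariate, protein-coding genes alone, other thresholds, leaving out each library, camera with an estimated correlation, and fry. Chosen after seeing the data were limma's voom on the recovered reads and the alternatives for the test of the genes near Aim2. The labels give no strain, sequencing batch, sex or housing. The library names share 1 stem within each genotype, so any cage or cohort that this stands for coincides with the genotype.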

Results

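Gene expression was measured by bulk RNA sequencing of tongues from mice that had drunk water with 100 µg/ml of 4NQO for 20 weeks. 4NQO (4-nitroquinoline 1-oxide) is a DNA-damaging carcinogen used to produce squamous lesions of the oral epithelium. There were 3 libraries from mice lacking Aim2 (Aim2 KO) and 3 from wild type mice, each numbered 1 to 3, and all 6 had received the carcinogen. Aim2 encodes a cytosolic sensor of double-stranded DNA that assembles an inflammasome. The recovered read totals ran from 21959204 reads in Aim2 KO replicate 3 to 25369400 reads in wild type replicate 3. The values were FPKM for 35275 genes, and 12144 genes with a mean of at least 1 FPKM were tested. The labels do not state whether each library came from its own mouse, so p-values measure the spread between these libraries. Values are given as mean ± SD of FPKM over the 3 libraries of a group, and log2 differences are Aim2 KO minus wild type on the log2(FPKM + 1) scale, which understates the change of low genes.

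The targeted gene was examined first. Aim2 (ENSMUSG00000037860; chromosome 1, 173350879 to 173466040, plus strand) was lower in each of the 3 Aim2 KO libraries than in any wild type library, at 0.0879 ± 0.063 FPKM against 0.327 ± 0.112 FPKM (n = 3 per group; exact permutation test, two-sided, p = 0.1, the smallest possible with 3 against 3). These levels rested on 3, 4 and 10 reads in the Aim2 KO libraries and on 14, 25 and 30 reads in the wild type libraries. The pooled read rate in Aim2 KO was 0.263 of that in wild type, with an exact 95% binomial interval of 0.145 to 0.452 that covers counting error only. It was 0.158 (interval 0.0614 to 0.344) without Aim2 KO replicate 3, which gave 10 of the 17 Aim2 KO reads. Aim2 lay below the expression filter, and without a filter its difference had an adjusted p of 0.9997 by limma. The sources used here do not say which exons the knockout removes, so reads from the remaining exons would still be counted.

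The comparison of the genotypes asked which tongue transcripts differ after carcinogen exposure when Aim2 is absent. Wdfy1, which encodes a FYVE-domain protein of early endosomes that acts in Toll-like receptor signalling, was higher in Aim2 KO, at 5.31 ± 0.604 FPKM against 1.14 ± 0.121 FPKM. Among the 12144 genes tested it was the 1 gene past the threshold, and 0 genes were lower. Its log2 difference was 1.55 (SE 0.13, limma adjusted p = 0.0341), and all 3 Aim2 KO libraries lay above all 3 wild type libraries. Wdfy1 (ENSMUSG00000073643) lies on chromosome 1 from 79702262 to 79776143 on the minus strand. It had the smallest p with pseudocounts of 0.1 and 0.5, but its adjusted p was 0.0501 with a filter at 0.1 FPKM, 0.21 without a filter, 0.0589 with vooma weights, 0.0718 after rescaling to TPM and between 0.295 and 0.405 when any library other than Aim2 KO replicate 1 was left out. At an unadjusted p under 0.05 there were 234 genes higher and 70 lower, 304 in all, where 607 would be expected with no difference. This total was 831 without Aim2 KO replicate 1, 794 with the skeletal muscle covariate and 1645 with array quality weights. The groups did not overlap for 605 genes higher and 180 lower in Aim2 KO, or 6.46% of the genes tested, where chance gives 10%.

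Of the genes next in order, none of which passed the threshold (adjusted p = 0.504 each), most encode antigen presentation or leukocyte proteins. Mcpt1, a mucosal mast cell protease, had 5.11 ± 1.87 FPKM in Aim2 KO and 0.816 ± 0.411 FPKM in wild type, although reads could be shared with its close relative Mcpt2. Coro1a, an actin-binding protein of leukocytes, had 9.65 ± 1.79 against 4.62 ± 0.665 FPKM, and Aif1, a macrophage marker, had 2.76 ± 0.751 against 0.742 ± 0.182 FPKM. Dynlt1b, a dynein light chain with near-identical copies beside it, had 8.12 ± 1.14 against 3.29 ± 0.901 FPKM. The others were Cd74, H2-Eb1, Tap1, H2-DMb1 and H2-Q7, described with their lists. In the other direction, Apoo, a protein of the mitochondrial inner membrane, had 19.1 ± 4.52 against 33.2 ± 2.80 FPKM (log2 difference -0.79, adjusted p = 0.882). Diap1 (ENSMUSG00000024456, named Diaph1 in GENCODE M21), which encodes a formin, had 13.9 ± 8.72 against 34.9 ± 1.84 FPKM (log2 difference -1.42, adjusted p = 0.9998). Its Aim2 KO values were 24.0, 8.78 and 8.90 FPKM. Without Aim2 KO replicate 1, the library with 24.0 FPKM, Diap1 passed with the smallest p of all genes tested (log2 difference -1.87, adjusted p = 0.000853). It also passed with the skeletal muscle covariate (adjusted p = 0.00404) and with array quality weights (adjusted p = 0.0109), and its adjusted p was 0.879 to 1 under the other alternatives. These fits are not independent of the one without Aim2 KO replicate 1. The skeletal muscle level was 7.32 in that library and 8.11 to 8.46 in the others, so the covariate largely sets it apart. Array quality weights are estimated from the same libraries. The same holds wherever these settings are given below. The remaining 8 genes on the lower side were Mafa, Otud1, Fam122a, Cabs1, Prr7, Lce1j, Vgll2 and Spef1, with log2 differences from -0.90 to -0.38, and none passed the threshold.

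**Figure D1:**
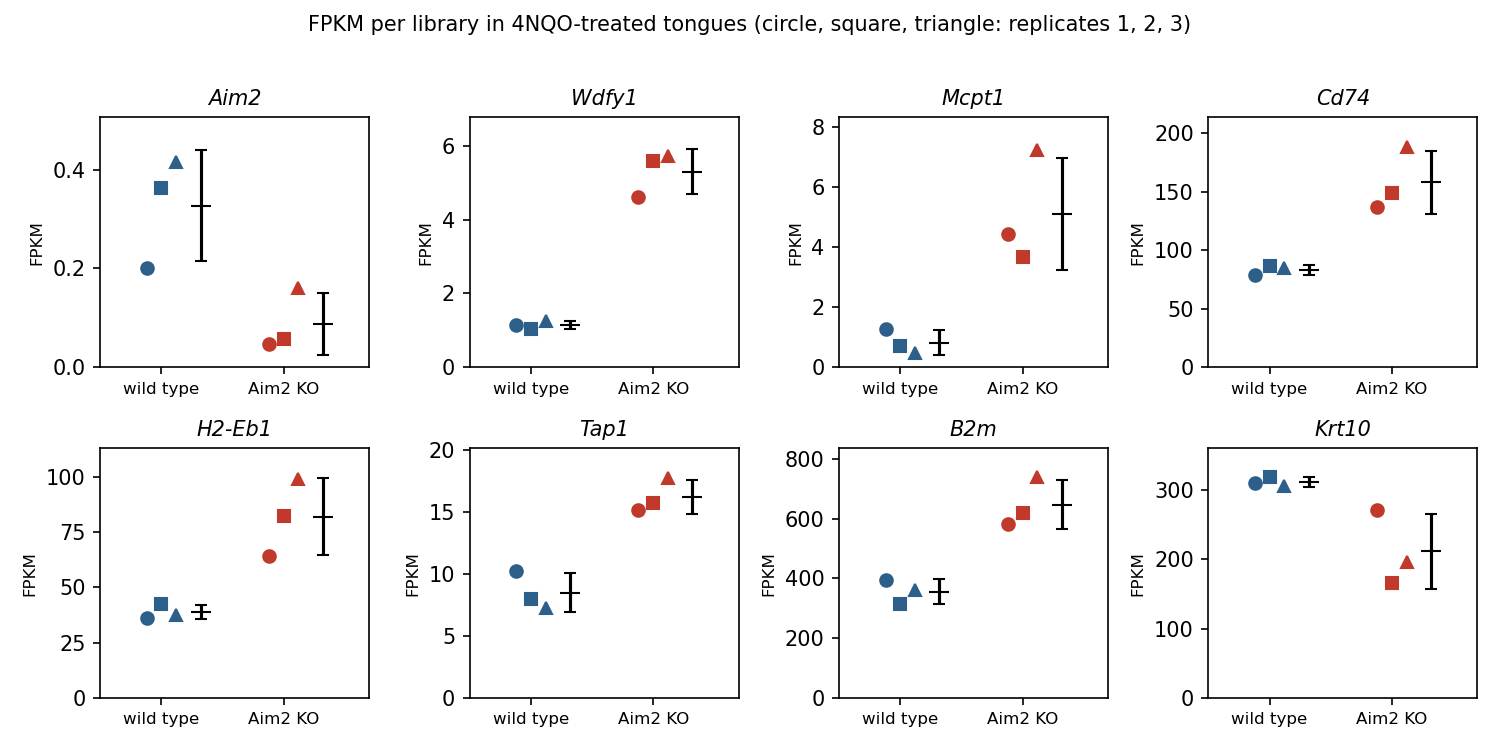
FPKM (y axes, linear from 0) of 8 genes in the 3 wild type (blue) and 3 Aim2 KO (red) libraries. Symbols mark single libraries by replicate number, and the black bars show the group mean ± SD. Wdfy1 was 5.31 ± 0.604 FPKM in Aim2 KO and 1.14 ± 0.121 FPKM in wild type, and it was the 1 gene of the 8 past the threshold.

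Genes of antigen presentation were higher in the Aim2 KO tongues. All 6 tested genes of the MHC class II list, which present extracellular peptides to CD4 T cells, were higher with no overlap of the groups, by a median log2 difference of 0.93. Cd74, the invariant chain, had 158 ± 27.0 FPKM against 83.4 ± 4.20 FPKM, and H2-Eb1 had 82.1 ± 17.5 against 38.8 ± 3.26 FPKM. H2-DMb1 had 7.52 ± 0.739 against 3.43 ± 0.871 FPKM and H2-Aa had 83.4 ± 20.3 against 39.2 ± 2.95 FPKM. All 27 tested genes of the list of interferon gamma response and MHC class I genes were also higher, by a median of 0.85, and for 20 of them the groups did not overlap. B2m, the light chain of class I molecules, had 647 ± 81.4 against 356 ± 40.3 FPKM. Tap1, a subunit of the peptide transporter, had 16.2 ± 1.37 against 8.50 ± 1.57 FPKM, and the GTPase gene Ifi47 had 4.38 ± 1.55 against 1.41 ± 0.150 FPKM. H2-Q7, whose reads could be split with other H2-Q genes, had 9.76 ± 2.29 against 4.51 ± 0.383 FPKM. Leukocyte markers were higher along with these genes. In a list of pan-leukocyte genes written after the data were seen, all 14 tested genes were higher, by a median of 0.67, and for 11 of them the groups did not overlap. Among all 12144 genes tested, 605 were higher without overlap. These counts are no test, because 4 genes of the list had been seen to be high before it was written and leukocyte genes can vary together. Without these 4 the median was 0.62.

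Both lists passed camera with a preset inter-gene correlation of 0.01 (adjusted p = 2.91e-19 for class II and 4.54e-42 for interferon gamma and class I). With an estimated correlation neither call held (adjusted p = 0.265 for each), and by fry the adjusted p was 0.0613 and 0.211. Adjusted over the list alone, 6 class II genes and 23 interferon gamma and class I genes passed, and over all genes tested 0 of either list did. Without Aim2 KO replicate 1, H2-Eb1, H2-Aa and Cd74 of the class II list and H2-Q6 and Ifi47 of the other list passed over all genes (adjusted p = 0.0256 to 0.0486). With array quality weights 5 and 14 genes did (adjusted p = 0.0109 to 0.0499), and with the skeletal muscle covariate H2-Eb1 and Ifi47 did (adjusted p = 0.0363 and 0.0395). The mean log2 level of each list was higher in 3 of 3 Aim2 KO libraries than in any wild type library (exact permutation test, two-sided, p = 0.1 for each). Such a separation was found for 6 of the 43 lists tested, all 6 higher in Aim2 KO, where chance gives 10%.

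The list of type I interferon response genes showed the same direction in all 28 tested genes, with a median log2 difference of 0.60. Some of the 28, such as Oas3, Zbp1, Ifi44 and Cmpk2, had wild type means under 1 FPKM. These reached the expression filter only through the Aim2 KO libraries. Irf7, the transcription factor of the type I response, had 8.08 ± 4.02 FPKM in Aim2 KO against 2.90 ± 0.897 FPKM, and Eif2ak2, the kinase PKR, had 4.56 ± 0.317 against 3.05 ± 0.365 FPKM. Parp14 had 2.81 ± 0.916 against 1.42 ± 0.223 FPKM and Cmpk2 had 1.60 ± 0.417 against 0.784 ± 0.308 FPKM. The list passed camera (adjusted p = 1.46e-20), but not with an estimated correlation (adjusted p = 0.514), and 0 genes passed adjusted over the list alone or over all genes. Aim2 KO replicate 1 did not share this level. Its mean log2 value was 1.77, below the 1.96 of wild type replicate 1 and the 1.80 of wild type replicate 2, while the other two Aim2 KO libraries were at 2.62 and 2.63. Without it Irf7 passed over all genes (adjusted p = 0.0379), and with array quality weights Irf7 and Parp14 did (adjusted p = 0.0326 and 0.0393).

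Other nucleic acid sensors were examined because Aim2 is one. All 6 tested genes of the Pyhin family, to which Aim2 belongs, had positive log2 differences (median 0.40), led by Ifi204 at 7.33 ± 2.63 against 4.20 ± 0.612 FPKM. This list passed camera (adjusted p = 0.000871), but not with an estimated correlation (adjusted p = 0.514), and reads of its close paralogs could be split between them. Of its 17 genes 6 were tested. Pyhin1 and Mnda had wild type means under 1 FPKM and reached the expression filter only through the Aim2 KO libraries. Among the 6 tested, Ifi204, Mndal and Mnda lie 0.40 to 0.55 Mb from Aim2, within the region examined below for flanking segments of another strain. The mean Pyhin level of Aim2 KO replicate 1 was 1.87, below the 1.90 and 1.95 of wild type replicates 1 and 3, while the other two Aim2 KO libraries were at 2.40 and 2.57. The mean log2 difference of 0.42 became 0.27 without Aim2 KO replicate 3 and 0.62 without Aim2 KO replicate 1. In the list of cytosolic nucleic acid sensing genes 10 of 14 were higher (median 0.17, camera adjusted p = 0.00147, adjusted p = 0.514 with an estimated correlation). Of the higher genes, Zbp1, Ifih1 and Ddx58 are also in the type I interferon list. The leading members of the sensing list were Samhd1, a dNTP hydrolase, at 21.1 ± 1.90 against 16.4 ± 0.511 FPKM, and Tmem173, which encodes STING, at 1.91 ± 0.318 against 0.869 ± 0.569 FPKM. The inflammasome and pyroptosis list did not pass (9 of 13 genes higher, median 0.06, camera adjusted p = 0.119). In these 3 lists 0 genes passed, adjusted over the list alone or over all genes, but Ifi204 passed over all genes with array quality weights (adjusted p = 0.0422). Casp1, the protease that inflammasomes activate, had 39.6 ± 1.57 against 31.6 ± 4.38 FPKM, and the adaptor gene Pycard had 57.2 ± 8.36 against 56.4 ± 8.94 FPKM. The cytokine genes Il1b and Il18 had 3.71 ± 2.08 against 1.82 ± 0.970 FPKM and 22.1 ± 8.09 against 23.6 ± 1.83 FPKM.

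Markers of several leukocyte types were higher in Aim2 KO. In the T cell list 6 of 7 tested genes were higher (median 0.32, camera adjusted p = 7.61e-05, adjusted p = 0.514 with an estimated correlation). Cd2, a T cell adhesion receptor, had 2.27 ± 1.06 against 0.410 ± 0.218 FPKM, and Trac, the T cell receptor alpha constant region, had 2.57 ± 1.64 against 0.492 ± 0.202 FPKM. These 2 genes passed adjusted over the list alone and 0 over all genes, although Cd2 did so with array quality weights (adjusted p = 0.0213). Trac was at 4.41 FPKM in Aim2 KO replicate 3 and at 2.04 and 1.26 FPKM in the other two. The more abundant T cell genes Trbc2, at 9.44 ± 4.25 against 9.53 ± 0.659 FPKM, and Cd5, at 5.89 ± 0.657 against 5.66 ± 0.615 FPKM, differed by less than the spread between libraries. The mean log2 difference of the list was 0.51, and 0.31 without Aim2 KO replicate 3. The list of checkpoint and regulatory T cell genes had 3 tested members, all higher (median 0.60, camera adjusted p = 0.000849, adjusted p = 0.321 with an estimated correlation). Cd274, which encodes PD-L1, had 2.63 ± 0.711 against 1.38 ± 0.315 FPKM and Tnfrsf4 had 2.08 ± 0.122 against 0.746 ± 0.576 FPKM, with 1.41 FPKM in wild type replicate 3 and 0.411 and 0.416 FPKM in the other two. These 2 passed adjusted over the list alone and 0 over all genes. All 6 tested genes of dendritic and Langerhans cells were higher (median 0.32, camera adjusted p = 0.000849, adjusted p = 0.265 with an estimated correlation), among them Itgax at 1.90 ± 0.923 against 0.869 ± 0.160 FPKM. This list alone passed fry (adjusted p = 0.019). Of the macrophage and monocyte genes 12 of 15 were higher (median 0.30, camera adjusted p = 0.000871, adjusted p = 0.702 with an estimated correlation). Ccr2 had 1.44 ± 0.501 against 0.703 ± 0.0494 FPKM and Cd68 had 6.40 ± 1.02 against 4.78 ± 0.793 FPKM. The mean macrophage level of Aim2 KO replicate 1, 2.76, was below all 3 wild type libraries (2.85 to 3.01), and both other Aim2 KO libraries were at 3.43. The mean log2 difference of 0.26 became 0.48 without Aim2 KO replicate 1, where C1qc and C1qa passed over all genes (adjusted p = 0.0367 and 0.0379), as C1qc did with array quality weights (adjusted p = 0.0389). It became 0.15 without Aim2 KO replicate 3 (adjusted p = 0.0247) and 0.15 without Aim2 KO replicate 2, where the macrophage call was lost (adjusted p = 0.131). With all 6 libraries neither the dendritic nor the macrophage list held a gene that passed, adjusted over the list alone or over all genes (0 in each). Many listed genes were not tested. Those tested were 7 of 20 T cell, 3 of 17 checkpoint, 6 of 15 dendritic and 15 of 22 macrophage genes. Cd2, Trac, Tnfrsf4, Itgax and Ccr2 had wild type means under 1 FPKM, so they reached the expression filter only through the Aim2 KO libraries. The same holds for Mcpt1, Aif1, Cmpk2 and Tmem173 above and for Ccl5 below.

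Inflammatory cytokines and chemokines were higher in 15 of 22 tested genes (median 0.44, camera adjusted p = 0.000871, adjusted p = 0.702 with an estimated correlation), with 0 genes passing adjusted over the list alone or over all genes. The members with the smallest p were chemokines that attract T cells and monocytes. Of these, Cxcl9 and Cxcl10 are also in the list of interferon gamma response and MHC class I genes. Cxcl9 had 7.61 ± 5.85 against 1.53 ± 0.626 FPKM, Cxcl10 had 19.1 ± 11.1 against 4.37 ± 3.36 FPKM, Ccl5 had 2.72 ± 1.63 against 0.470 ± 0.416 FPKM and Ccl2 had 8.06 ± 7.26 against 1.96 ± 0.653 FPKM. Single libraries carried some of these means. Cxcl9 was at 4.00, 4.48 and 14.4 FPKM and Ccl2 at 16.3, 2.67 and 5.19 FPKM in Aim2 KO replicates 1, 2 and 3, and Cxcl10 was at 8.11 FPKM in wild type replicate 1 and at 3.43 and 1.58 FPKM in the other two. With array quality weights Ccl5 and Cxcl9 passed over all genes (adjusted p = 0.0362 and 0.0389). With the same weights the camera direction of the list turned and its call was lost (mean log2 difference 0.18, camera adjusted p = 0.78). The neutrophil attractant Cxcl1 had 31.7 FPKM in Aim2 KO replicate 1 and between 1.90 and 7.73 FPKM in the other 5 libraries. Without that library the camera direction of the list turned (mean log2 difference 0.13, adjusted p = 0.26), and without wild type replicate 2 the call was lost (adjusted p = 0.0996).

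Keratinisation genes were lower on average in Aim2 KO, but not in each library. In this list of terminal differentiation and cornified envelope genes, 22 of 26 had negative log2 differences (median -0.21, camera adjusted p = 1.42e-06, adjusted p = 0.514 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. Krt10, a suprabasal keratin, had 212 ± 54.5 against 312 ± 6.87 FPKM, and Lor, the cornified envelope protein loricrin, had 1967 ± 144 against 2706 ± 159 FPKM. Klk7 had 32.4 ± 10.5 against 43.9 ± 6.45 FPKM and Lce3a had 248 ± 53.3 against 351 ± 111 FPKM. The mean keratinisation level of Aim2 KO replicate 1 was 8.48, above the 8.18 and 8.39 of wild type replicates 2 and 3, while the other two Aim2 KO libraries were at 8.06 and 7.87. The mean log2 difference of -0.24 became -0.11 without Aim2 KO replicate 3 (camera adjusted p = 0.0432) and -0.15 without wild type replicate 1. It became -0.42 without Aim2 KO replicate 1, where Krt1 passed over all genes (log2 difference -1.57, adjusted p = 0.0256). With array quality weights Krt10 did (adjusted p = 0.0473). The basal keratinocyte list did not pass (8 of 16 genes higher, camera adjusted p = 0.363), nor did the list of papilla hair type keratins (3 of 12 higher, camera adjusted p = 0.0712).

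Skeletal muscle, the main tissue of the tongue below the epithelium, was lower by camera in 21 of 22 tested genes (median -0.23, adjusted p = 5.25e-05, adjusted p = 0.727 with an estimated correlation). Myh1, a fast myosin heavy chain, had 571 ± 114 against 802 ± 142 FPKM. Also lower were the lists of nuclear genes of oxidative phosphorylation (23 of 24, camera adjusted p = 0.000259), the mitochondrial genome (11 of 12, camera adjusted p = 0.00122), muscle regeneration (7 of 7, camera adjusted p = 0.00122) and adipocytes (9 of 10, camera adjusted p = 0.013). With an estimated correlation their adjusted p values were 0.74, 0.727, 0.702 and 0.727. The skeletal muscle level of Aim2 KO replicate 1 was 7.32 on the log2 scale, where the other 5 libraries lay between 8.11 and 8.46. Without that library the muscle list had a mean log2 difference of 0.13 (adjusted p = 0.502), and none of the 5 lists was called. The muscle mean of -0.22 became -0.44 without Aim2 KO replicate 2 and -0.36 without Aim2 KO replicate 3. The means of oxidative phosphorylation and adipocytes, -0.12 and -0.14, became -0.20 and -0.32 without Aim2 KO replicate 2 and -0.22 and -0.24 without wild type replicate 3. That of the mitochondrial genome, -0.17, became -0.27 without Aim2 KO replicate 3. Without wild type replicate 2 the calls of oxidative phosphorylation, muscle regeneration and adipocytes were also lost (adjusted p = 0.17, 0.167 and 0.171), and that of adipocytes was lost without Aim2 KO replicate 3 or wild type replicate 1 as well (adjusted p = 0.0671 and 0.123). Adjusted over the list alone or over all genes, 0 of their genes passed.

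Proliferation genes were higher in 26 of 30 tested genes (median 0.21, camera adjusted p = 1.85e-05, adjusted p = 0.727 with an estimated correlation). Top2a, a DNA topoisomerase of dividing cells, had 18.2 ± 1.49 against 13.1 ± 3.32 FPKM and the cyclin gene Ccnb2 had 10.2 ± 2.04 against 7.25 ± 0.771 FPKM. Without Aim2 KO replicate 1 the proliferation list was no longer called (adjusted p = 0.542), and its mean log2 difference of 0.18 became 0.10 without that library and 0.27 without wild type replicate 3. Genes of the NRF2 and xenobiotic response were higher in 14 of 18 (median 0.22, camera adjusted p = 0.0216, adjusted p = 0.789 with an estimated correlation). Gsta1, a glutathione transferase, had 612 ± 143 against 455 ± 96.2 FPKM. The mean log2 difference of 0.16 became 0.28 without Aim2 KO replicate 3, 0.26 without wild type replicate 1, and 0.09 without Aim2 KO replicate 1 or wild type replicate 2. Leaving out Aim2 KO replicates 1 or 2 or wild type replicates 2 or 3 ended that call (adjusted p = 0.754, 0.341, 0.374 and 0.199). With array quality weights the mean log2 difference of the NRF2 list turned to -0.05, with a camera adjusted p of 0.0446. In both lists 0 genes passed, adjusted over the list alone or over all genes.

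In all, 12 of the 43 testable lists were called higher and 6 lower with the preset correlation, and 0 were called with an estimated one. Some lists share genes, so these calls are not independent of each other. The other 25 lists had camera adjusted p values between 0.0712 and 0.972. Among them were B cells and plasma cells (median log2 difference 0.20, adjusted p = 0.0712), mast cells and eosinophils (0.43, adjusted p = 0.0799), neutrophils (-0.01, adjusted p = 0.515), targets of p53 (0.03, adjusted p = 0.939), stress keratins and wound response (-0.02, adjusted p = 0.939), matrix remodelling and invasion (0.07, adjusted p = 0.913), epithelial mesenchymal transition (0.04, adjusted p = 0.939) and glycolysis and hypoxia (0.04, adjusted p = 0.72). For 5 of the 43 lists the median and the mean log2 difference had opposite signs, and none of these 5 was called.

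**Figure D2:**
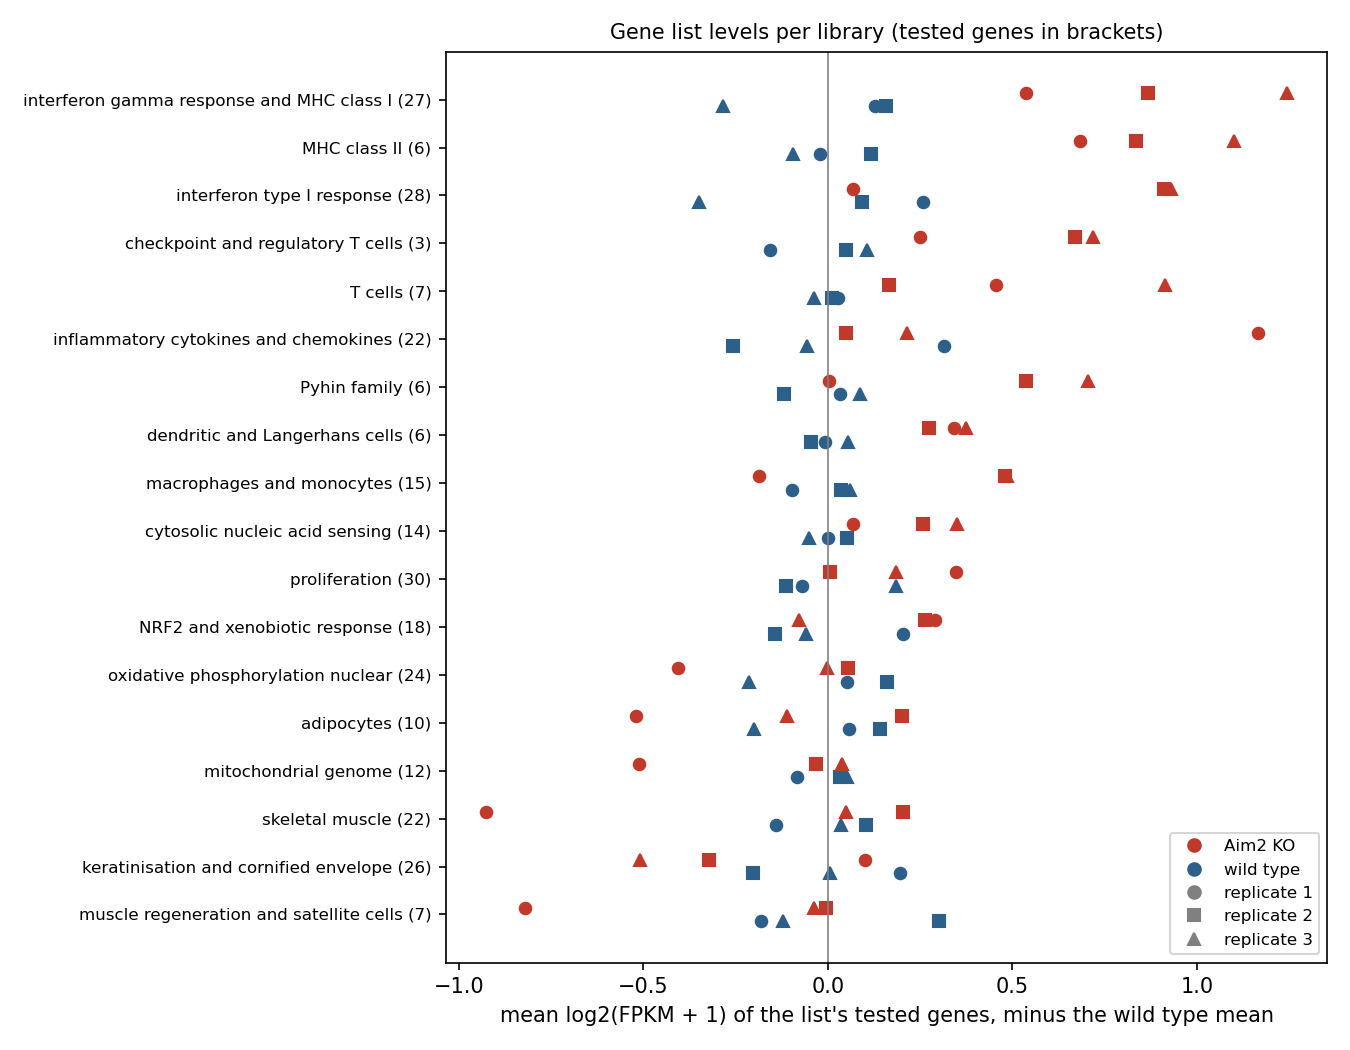
Mean log2(FPKM + 1) of the tested genes of the 18 called lists per library, minus the wild type mean (x axis, log2 units), with 1 row per list and the number of tested genes in brackets. Red symbols are Aim2 KO and blue symbols wild type libraries, with shapes for replicates 1 to 3. All 3 Aim2 KO libraries lie above all 3 wild type libraries for MHC class II and for interferon gamma response and MHC class I. The same holds for T cells, checkpoint and regulatory T cells, dendritic and Langerhans cells, and cytosolic nucleic acid sensing. Aim2 KO replicate 1 alone is low for skeletal muscle (7.32 against 8.11 to 8.46 before the subtraction).

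The libraries were compared by principal components. The first component held 51.7% of the variance and set Aim2 KO replicate 1 (35.4) apart from the other 5 libraries (-19.2 to 5.39), without separating the genotypes (exact permutation test, two-sided, p = 0.9). The second held 16.5% and placed the 3 Aim2 KO libraries (4.33 to 17.1) above the 3 wild type libraries (-12.2 to -2.98; exact permutation p = 0.1). Spearman correlations over genes were 0.952 to 0.985 within groups and 0.956 to 0.985 between groups, and genes are not independent replicates. In Aim2 KO replicate 1 the collagen gene Col3a1 was at 1.57 FPKM against 3.25 to 11.3 FPKM in the other 5 libraries. S100a8, a calprotectin subunit of neutrophils and stressed epithelium, was at 3040 FPKM there and at 363 to 1575 FPKM in the others.

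**Figure D3:**
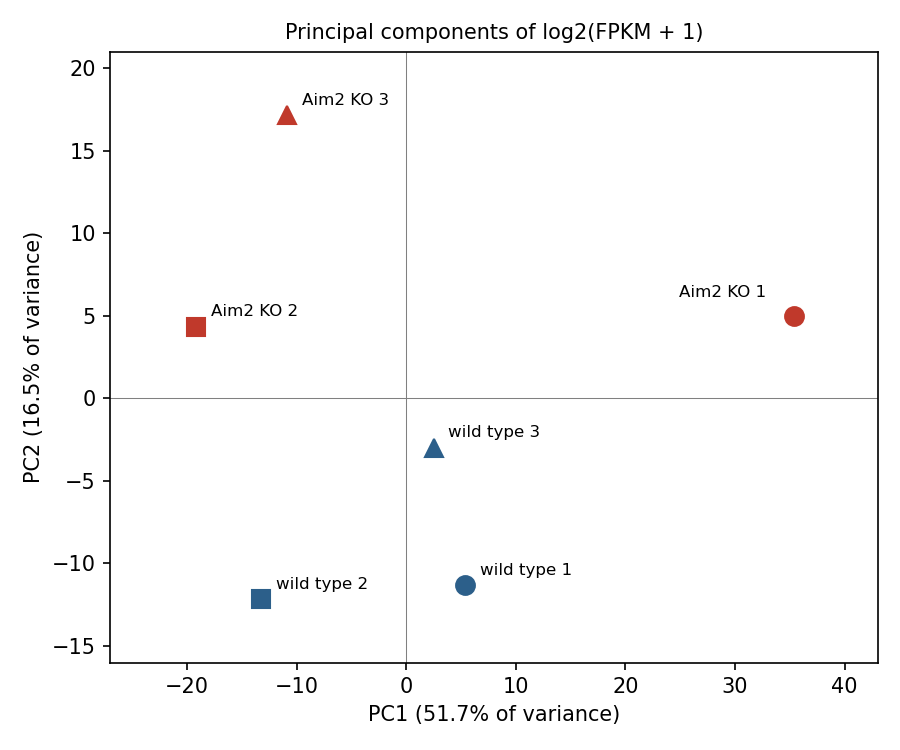
First 2 principal components of log2(FPKM + 1) over 12144 genes, with the share of variance on each axis, for the 3 Aim2 KO (red) and 3 wild type (blue) libraries. Aim2 KO replicate 1 lies at 35.4 on the first component, and the other 5 libraries lie between -19.2 and 5.39.

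A knockout can carry flanking chromosome segments from the strain in which it was made, so the genes near Aim2 were tested as a group. Within 20 Mb of Aim2, 0 of 217 tested genes passed the adjusted threshold, against 1 of 11927 elsewhere (Fisher's exact test, two-sided, p = 1). At an unadjusted p under 0.01 there were 2 of 217 near Aim2 (0.922%) and 68 of 11927 elsewhere (0.57%; Fisher's exact test, two-sided, p = 0.357). Both genes near Aim2, Fcer1g and Cd48, are expressed in leukocytes. Without Aim2 KO replicate 1 the share near Aim2 was 14 of 217 (6.45%) against 277 of 11927 elsewhere (2.32%; Fisher's exact p = 0.000744). Of these 14 genes 12 were higher, among them the Fc receptor genes Fcgr2b, Fcer1g, Fcgr4 and Fcgr3 and the Pyhin genes Ifi204, Mndal and Mnda. Fisher's exact test takes genes as independent, but the genes of these 2 families lie close together and could vary together. Its p therefore cannot tell a segment of another strain from a shared change of such genes.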

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

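Chosen after seeing the data were voom on the recovered reads and the alternatives for the genes near Aim2. With 3 libraries per group the number of genes called depends on single settings and libraries. The 1 gene higher became 0 without an expression filter, with a filter at 0.1 FPKM, after TPM rescaling, with vooma weights and with the replicate block. It became 65 with array quality weights and 3 with the skeletal muscle covariate. The 0 genes lower became 3 and 1 under these last settings. Leaving out 1 library at a time gave 0 to 12 genes higher and 0 to 2 lower, with the highest counts without Aim2 KO replicate 1. In every one of these settings Wdfy1 ranked first or second by p. Its adjusted p over all settings ran from 0.000857 to 0.405. With no filter 22220 genes were tested and the unadjusted p of Wdfy1 was 1.61e-05, against 2.81e-06 with it. The cause was not tested. Voom called 1 gene higher and 0 lower. At an unadjusted p under 0.05 there were 831 genes without Aim2 KO replicate 1, between 228 and 427 without any other library, 794 with the muscle covariate and 1645 with array quality weights.

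The replicate block gave 0 genes higher and 0 lower (Wdfy1 adjusted p = 0.252), 14 lists higher and 7 lower. The same numbers did not pair the libraries: the correlations of deviations from the group means were 0.351, 0.459 and 0.0302 for numbers 1, 2 and 3, and each library of number 3 correlated better with a library of another number.

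The 12 lists higher and 6 lower became 0 and 0 with an estimated correlation and 1 and 0 by fry, and fry's test for change in either direction called 0. The estimated correlation was 0.573 for interferon gamma and MHC class I and -0.134 for dendritic cells, against the preset 0.01. Under the other settings 12 to 17 lists were called higher and 5 to 9 lower. Leaving out libraries gave 12 to 16 and 5 to 8. The lists of MHC class II, interferon gamma, type I interferon, nucleic acid sensing, Pyhin, T cell, checkpoint, dendritic cell and keratinisation genes kept their call under all 21 settings other than these set tests. Without Aim2 KO replicate 1, 10 of the 18 lists were still called in the same direction. Either the sign of the mean log2 difference or the direction of camera then turned for 5 lists and 3 genes. With each library left out in turn the mean ran from 0.132 to 0.69 for inflammatory cytokines, from -0.438 to 0.127 for skeletal muscle, from -0.225 to 0.0253 for nuclear oxidative phosphorylation, from -0.272 to 0.00374 for the mitochondrial genome and from -0.316 to 0.0449 for adipocytes. The log2 difference ran from -0.578 to 0.00964 for Pygm, from -0.357 to 0.0144 for Sdha and from -0.45 to 0.00501 for Plin4. With array quality weights a sign or direction turned for inflammatory cytokines (0.184), skeletal muscle (0.0502), the mitochondrial genome (0.0181), NRF2 (-0.0456), Ttn (0.045), Myod1 (0.0616) and Gsta2 (-0.0449). Of these lists NRF2 alone was then past the camera threshold (adjusted p = 0.0446). The cause was not tested.

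The Aim2 level, a log2 difference of -0.28, moved to -1.20 and -0.49 with pseudocounts of 0.1 and 0.5 and to -0.48 after TPM rescaling, as the pseudocount outweighs so low a gene. The share of genes near Aim2 with an unadjusted p under 0.01 was 5.07% with the skeletal muscle covariate (Fisher's exact p = 0.00748) and 0% to 6.45% with 1 library left out. That test takes genes as independent, which neighbouring genes need not be. Of 1804 values of the 86 genes named by rule under alternatives 1757 kept direction and side of the threshold, 31 newly passed, 10 no longer passed and 6 turned in direction. Wdfy1 was the 1 gene past the threshold in the main fit, so all 10 losses were its own. The 1757 values are mostly genes that passed in neither fit, so this count does not measure how stable a call is.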

Other observations

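Tests chosen only after the result was seen were those on the H2 genes of chromosome 17, single libraries, leukocytes, the splits for MHC and interferon gamma genes, and all those on Aim2 KO replicate 1; the tests on Nnt, on the neighbours of Wdfy1 and on the splits for counts of genes and lists were set before. Among other values, genes of connective tissue mast cells had wide spreads: Mcpt4 was at 6.09 ± 3.38 FPKM in Aim2 KO and 3.93 ± 1.12 FPKM in wild type, and Cpa3 at 1.84 ± 0.983 against 0.899 ± 0.0945 FPKM. The mucosal proteases Mcpt1 and Mcpt2 rested on 360 and 150 reads in the Aim2 KO libraries and 62 and 28 in wild type. Ifng itself was below the filter, with 27 reads in Aim2 KO and 8 in wild type. Diap1 had 8.78 and 8.90 FPKM in Aim2 KO replicates 2 and 3, 24.0 FPKM in replicate 1 and 33.1 to 36.8 FPKM in wild type. The Y-linked gene Ddx3y was at 11.0 to 14.6 FPKM in all 6 libraries, and Xist had 5 reads or fewer in each. The Y-linked genes Eif2s3y, Kdm5d and Uty were also expressed in each library. These are values of male tissue in both groups, although the labels do not give the sex. Il17a, at 5.53 FPKM, and Ccl20, at 6.92 FPKM, were highest in Aim2 KO replicate 1, where the other 5 libraries reached 1.81 and 1.01 FPKM.

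The higher MHC and interferon gamma genes were weighed against 3 explanations. Alleles of another strain at the H2 genes would leave members elsewhere near 0, but the 17 tested members off chromosome 17 were all higher, with a median log2 difference of 0.90 (0.73 or more with any library left out), and a single library does not carry the pattern either, since the lowest median with 1 library left out was 0.73 against 0.86 with all 6. A larger share of leukocytes stays open: 14 tested genes of a list of 20 pan-leukocyte genes, none of which is in a fixed list, had a median of 0.67, below the 0.93 of class II but over 0.5 of it, and 0.62 without the 4 genes already seen to be high when the list was written; its most abundant members were Cd52, Tyrobp and Lcp1 at 16.5, 10.4 and 10.1 FPKM in Aim2 KO. A response to the genotype, or to a cage or cohort that coincides with it, is also a candidate explanation, and it was not tested, because each genotype has 1 library name stem. It does not exclude a larger share of leukocytes, which could be part of such a response. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05: the mean log2 difference of these genes was 0.88 in the real split (1 of 10 splits this large) and at most 0.61 in the others.

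For Wdfy1, a change of the whole region is argued against by the 4 tested genes within 1 Mb, Cul3, Mrpl44, Serpine2 and Ap1s3, which differed by at most 0.17 on the log2 scale. A substrain difference between the colonies stays open, since Nnt, which carries a deletion in C57BL/6J, had a log2 difference of -0.37 with overlapping groups (13.0 ± 3.75 against 16.7 ± 2.15 FPKM). Its size depends on single libraries, being -0.13 without Aim2 KO replicate 1, -0.29 without wild type replicate 2 and between -0.52 and -0.34 without any other, so it was not under 0.3 with each library left out, as set beforehand for excluding a substrain difference. Nor did Nnt differ by over 1 on the log2 scale without overlap of the groups, as set beforehand in favour of a substrain difference. That test rested on Nnt alone. Ide and Entpd4 were looked up beside it. Ide had a log2 difference of -0.06 with overlapping groups (62.3 ± 10.4 against 64.9 ± 8.63 FPKM). Entpd4 had 0 reads in each library and cannot show a difference. Wdfy1 lies 93.7 Mb from Aim2, and a variant of Wdfy1 itself may account for its level as well as the loss of Aim2 may. Of the 10 splits 2 called any gene: the real one called 1, and the one that joins Aim2 KO replicate 1 with wild type replicates 1 and 3 called 3, and the 10 splits are too few for a share under 0.05.

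Aim2 KO replicate 1 stood apart on the first component. Lower depth is argued against, because the library with the fewest reads, Aim2 KO replicate 3 with 21959204, lies on the other side. A smaller share of muscle and stroma in the piece is a candidate explanation: all 4 lists of muscle, fibroblasts, endothelium and Schwann cells were below every other library, with log2 levels of -0.98, -0.96, -0.77 and -1.08 relative to the mean of the other 5, in that order. Measured against basal keratinocytes alone, it does not account for the inflammatory genes. Their list rose over the other 5 by 0.88 more than the basal keratinocyte list did, where the SD of that gap among the other 5 was 0.28. The basal list does not cover other epithelial layers, and the list of stress keratins and wound response was also highest in this library (6.80 against 5.93 to 6.52). No biological explanation, such as a lesion in that tongue, was tested. The splits show this structure: the real split called 18 lists with the preset correlation and other splits up to 28 (5 of 10, the real one included, called 18 or more), and the split that joins Aim2 KO replicate 1 with wild type replicates 1 and 3 gave 1886 genes at an unadjusted p under 0.05, against 304 in the real one. The 10 splits are too few for a share under 0.05.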
